A study of Homo sapiens with 6 samples.

How the data were processed

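RNA-seq values of 6 libraries from NCI-H460 cells, an established human non-small cell lung cancer line, were analysed. Per the labels, 3 libraries came from cells with a control short hairpin RNA (shControl) and 3 from cells with a short hairpin RNA against APE1 (shAPE1), whose gene is APEX1. Per the labels' protocols, total RNA was purified on columns and libraries were prepared with a kit for mRNA sequencing. The labels do not say whether the numbered libraries of a group came from separate cultures or separate hairpins, so the p-values measure only the spread between these libraries, which may be technical.

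The authors deposited 1 table of 30145 genes with a raw count and an FPKM value for each library. Per the file headers, the first kind of column holds counts, and the values are whole numbers that are not normalized. Per the file headers, the second kind holds FPKM, fragments scaled to gene length and library depth, as deposited by the authors. The aligner, the counting program, its use of strand and its treatment of reads with several positions are not given in the sources used here. The submitters' processing notes name the mouse builds GRCm38 and mm10. All 30145 gene identifiers in the table are human Ensembl identifiers, 29411 of them occur in GENCODE release 29 on GRCh38, and 86% of those have the same chromosome and the same start or end there. Coordinates are printed as the table gives them and are read as GRCh38 on that ground. Reads of overlapping genes, of antisense partners and of near-identical copies could be assigned to either member. Of 152 genes that the rule below names, 25 overlap another gene with at least 10% of their own mean count. Among those printed, these are APEX1, LGR5, IFIT1, IFIT2, IFIT3, BEST1, FEN1, TYMS, KIF20A, HLA-B, KRT8, KRT18, CD68, MT-ATP6, MT-ATP8 and MT-CO3, and their values are uncertain to that extent.

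Genes with a mean FPKM of at least 1 over the 6 libraries were tested, 10819 in all. Counts were scaled by the trimmed mean of M-values and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, two-sided, 4 residual degrees of freedom), with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The plan written before the data were examined named limma on log2(FPKM + 0.5), to be replaced by edgeR if the table held raw counts, which it did. CPM values are counts divided by the scaled library size and multiplied by 1e6, and every mean ± SD has n = 3. Log2 fold changes are shAPE1 minus shControl. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic.

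Before the data were examined, 44 gene lists were fixed, among them markers of other cell types. Lists with at least 5 tested members, 40 in all, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 0.5 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The GO, KEGG and Reactome terms that the table pairs with its genes were tested in the same way, 3064 terms of 15 to 300 tested genes. The rule for named genes, fixed at the same time, took APEX1, then the 12 largest rises and 12 largest falls among called genes with at least a 2-fold change and FPKM ranges that did not overlap, leaving out clone, LOC, LINC, antisense and pseudogene names. It then took up to 4 called members of each list with the smallest adjusted p, or up to 2 members with the highest mean FPKM where none was called. Other genes are said to have been chosen after their values were seen. Some items that these rules name are not reported here.

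Total counts ranged from 64192187 to 67542609 per library, and 3 counts, the limit that a count of 0 allows, correspond to 0.044 to 0.047 CPM. Such limits cover counting error only. The fits were tested on simulated counts for the 10819 genes in this comparison, with 200 genes changed. The edgeR fit recovered 36 of 67 genes changed 1.5-fold, 65 of 67 changed 2-fold and 66 of 66 changed 4-fold, with 19 false calls. The false share of its calls was thus above the threshold of 0.05 in this run. In the data 3128 genes were called, far more than the 200 changed here, so these shares do not carry over to the data. With the type I interferon list lowered 2-fold in simulated counts for these genes, camera called 1 of 40 lists. The simulation drew genes independently, so it does not test the preset correlation.

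No libraries were duplicates. Over genes with at least 20 counts in a pair, the chi-square per degree of freedom was 31.2 between shControl 1 and shControl 3, 117 and 121 between shControl 2 and these, and 24.1 to 39.3 between shAPE1 libraries. Alternatives were other pseudocounts, FPKM filters, scalings and tests, DESeq2 1.42.0, the replicate number as a block, and each library left out in turn. Pseudocounts, TPM and quantile scaling apply to log2 FPKM, so these alternatives used limma. Scaling by total counts and leaving out read-through genes were added after the data were seen.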

Results

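Gene expression was measured by RNA-seq in NCI-H460 cells, a human non-small cell lung cancer line, in 3 libraries from cells with a control hairpin and 3 from cells with a hairpin against APE1. APE1 is the main AP endonuclease of base excision repair and also acts as a redox regulator of transcription factors. Total counts per library lay between 64192187 and 67542609, and mitochondrially encoded genes took 8.49% to 9.25% of them. The comparison asks which transcripts differ between cells with the APE1 hairpin and cells with the control hairpin.

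APEX1 (ENSG00000100823, chromosome 14, 20455191 to 20457772, plus strand), the targeted gene, was lower in all 3 shAPE1 libraries than in any control. Its level was 219 ± 15.6 CPM (SD, n = 3) in shControl and 151 ± 4.2 CPM (SD, n = 3) in shAPE1, a 1.45-fold fall (log2 fold change -0.53, SE 0.10, adjusted p = 0.00113 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). APEX1 overlaps PIP4P1 on the opposite strand, which had a log2 fold change of 0.22 (SE 0.11). Of the tested members, 16 of 21 type I interferon genes, 25 of 28 integrated stress response genes and 20 of 23 immediate early genes fell, with OASL, CHAC1 and EGR1 lower by larger factors than APEX1. Of S phase and E2F genes 18 of 30 rose and of heat shock genes 13 of 18, and these 5 lists were called by camera at both the preset and the estimated correlation. The lists of mitosis and of cholesterol synthesis, with 16 of 29 and 11 of 22 members higher, were called at the preset correlation only.

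**Figure D1:**
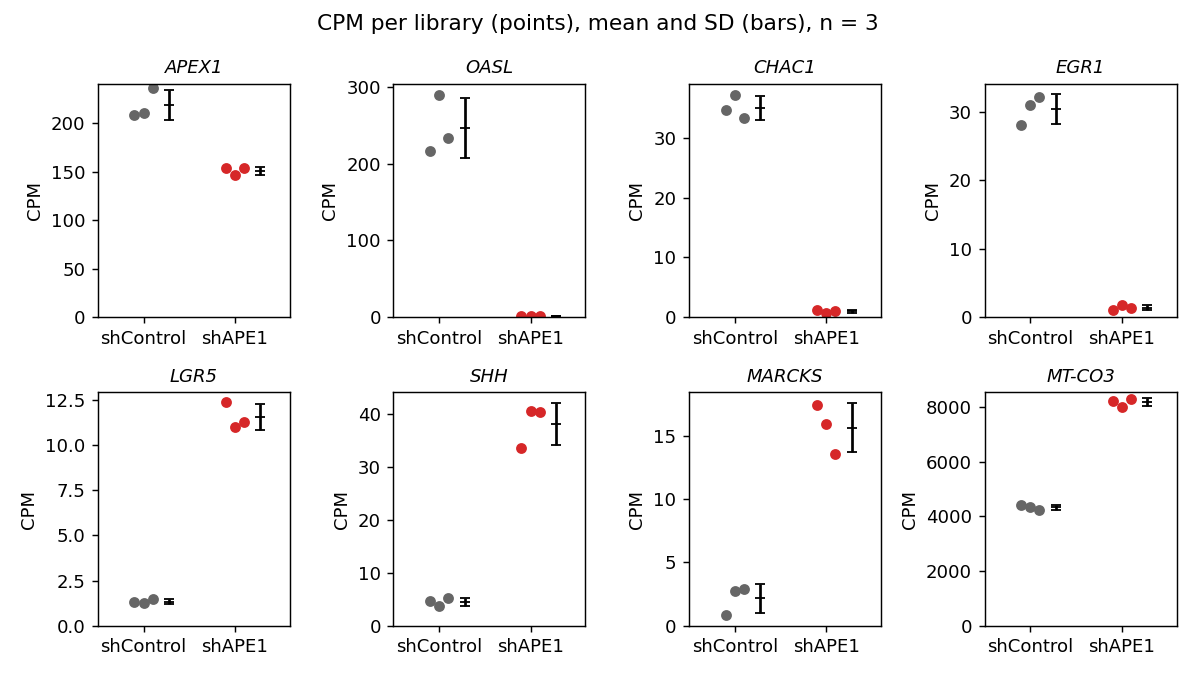
Depth-scaled counts (CPM, linear axes from 0) of 8 genes in each library, with points for single libraries and bars for the mean and SD of 3 libraries. APEX1 fell 1.45-fold, OASL, CHAC1 and EGR1 fell 173-fold, 36.3-fold and 22.7-fold, and LGR5, SHH, MARCKS and MT-CO3 rose, with no overlap between groups.

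Of 10819 genes tested, 3128 passed the threshold, 1384 higher and 1744 lower in shAPE1, a split that turned to 1775 higher and 1558 lower with limma on quantile-normalized values. A change of at least 2-fold was found for 412 of these, 93 higher and 319 lower, so that 77.4% of the larger changes were falls. At 4-fold or more, 13 genes rose and 99 fell. The libraries of the groups did not overlap for 46% of tested genes, where chance gives 10%. The control libraries were less alike than the shAPE1 libraries, and shControl 2 stood apart from the other controls. Without it 3937 genes passed, and without shAPE1 1, shAPE1 2 or shAPE1 3 the count was 2041, 2085 or 2100.

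The steepest fall among the named genes was that of OASL, an interferon-induced member of the oligoadenylate synthetase family, from 246.5 ± 38.7 CPM to 1.42 ± 0.25 CPM (log2 fold change -7.43, SE 0.18, adjusted p = 1.93e-12 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). IFIT2, IFIT1 and IFIT3, which are adjacent interferon-induced genes on chromosome 10, fell 78.7-fold, 46.9-fold and 36-fold. In the type I interferon list 16 of 21 tested members fell, none rose and 5 did not pass, with 17 lower when adjusted over the list alone. The list's median log2 fold change was -0.99 and its mean was -2.28, and camera gave an adjusted p of 3.57e-15, or an adjusted p of 0.0333 with an estimated correlation. ISG15, a ubiquitin-like modifier, fell 17.4-fold. The chemokine CCL5 fell 39.9-fold, and the DNA sensor CGAS fell 2.19-fold from 6.49 to 2.97 CPM. Both belong to the list of cytosolic DNA sensing and inflammasome genes, in which 4 of 8 members fell, or 5 adjusted over the list alone (camera adjusted p = 0.00959, and adjusted p = 0.133 with an estimated correlation).

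In the antigen presentation list 7 of 15 members fell and none rose, with 8 lower when adjusted over the list alone (camera adjusted p = 0.000261, and adjusted p = 0.291 with an estimated correlation). CD274, which encodes the checkpoint ligand PD-L1, fell 10-fold from 57.1 ± 11.1 to 5.71 ± 0.32 CPM. HLA-B fell 1.75-fold, and this value is uncertain because genes of this family share near-identical sequence. Markers of leukocytes were mostly below the expression limit, with 2 of 12 tested. Of these CD68, a lysosomal protein of macrophages that other cells also express, fell 1.49-fold. The other, LYZ, chosen after its values were seen, had 1.71 CPM in shControl and 2.5 CPM in shAPE1 and did not pass.

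Genes of the integrated stress response, which ATF4 drives when amino acids are short or translation initiation is inhibited, fell as a group: 25 of 28 members were lower, none was higher and 3 did not pass, with 26 lower when adjusted over the list alone. Their median log2 fold change was -1.13 (camera adjusted p = 1.67e-24, and adjusted p = 0.046 with an estimated correlation). CHAC1, a glutathione-degrading enzyme, fell 36.3-fold from 35.2 ± 2.0 to 0.97 ± 0.24 CPM. TRIB3, a pseudokinase, fell 5.91-fold, SESN2, a sestrin, fell 6.63-fold, and GDF15, a stress-induced cytokine, fell 6.28-fold. By contrast, the list of endoplasmic reticulum chaperones and sensors had 3 members higher and 3 lower of 26 (1 and 2 adjusted over the list alone; camera adjusted p = 0.783), with XBP1, a transcription factor of that response, 1.89-fold lower. Among p53 targets 8 of 26 fell and none rose, or 9 adjusted over the list alone (camera adjusted p = 0.00959, and adjusted p = 0.178 with an estimated correlation). The members that fell most, PMAIP1 at 6.96-fold, SESN2 and GDF15, include genes that the integrated stress response list also holds.

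Immediate early genes and AP-1 components, which respond to growth factor and stress signals, fell in 20 of 23 cases and rose in 2, with the same counts adjusted over the list alone (median log2 fold change -0.75, camera adjusted p = 4.97e-13, and adjusted p = 0.0488 with an estimated correlation). EGR1, a zinc-finger transcription factor, fell 22.7-fold, DUSP1, a MAP kinase phosphatase, fell 9.12-fold, and ATF3 fell 6.52-fold. KLF2 and KLF6, chosen after their values were seen, were the members that rose, with log2 fold changes of 0.82 and 0.46. Among NF-kB targets 12 of 20 fell and none rose, with 12 lower and 1 higher when adjusted over the list alone (camera adjusted p = 4.68e-08, and adjusted p = 0.0816 with an estimated correlation). The cytokines CXCL2, CXCL8 and IL6 fell 8.62-fold, 5.28-fold and 4.77-fold, CXCL8 from 1097 ± 41.9 to 208 ± 24.8 CPM. In the senescence-associated secretory list, which shares these cytokines, 20 of 25 fell and 1 rose, also over the list alone (camera adjusted p = 1.88e-14, and adjusted p = 0.054 with an estimated correlation). Of YAP and TEAD targets 11 of 19 fell and 1 rose, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.00298, and adjusted p = 0.103 with an estimated correlation). With a mean FPKM of at least 5, which left 10 members, this list was not called (camera adjusted p = 0.0695, median log2 fold change -0.41). NT5E, an ectonucleotidase, fell 4.56-fold and the matricellular gene CCN2 fell 2.37-fold.

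**Figure D2:**
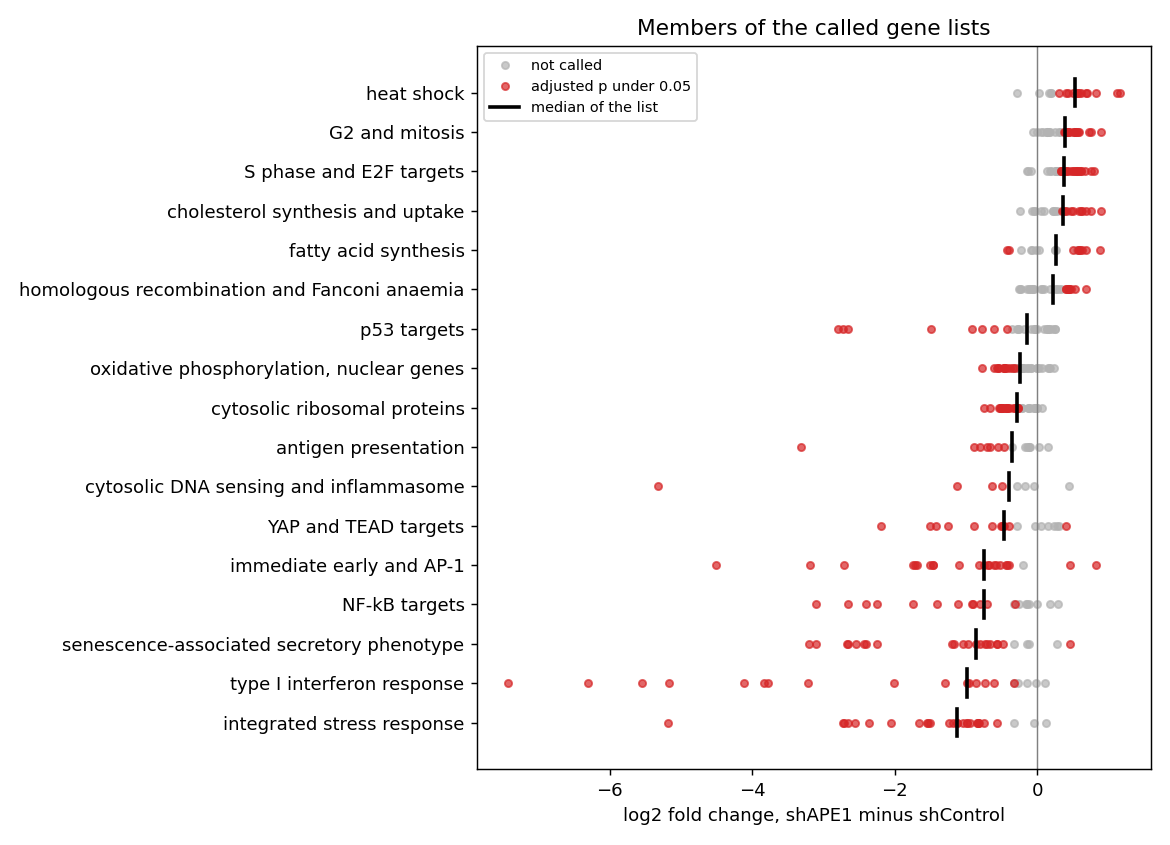
Log2 fold changes (shAPE1 minus shControl, horizontal axis) of the tested members of the 17 called lists, with red points for genes with adjusted p under 0.05, grey points for the others and a black line at each list's median. The medians run from -1.13 for the integrated stress response to 0.53 for heat shock.

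In the S phase and E2F list 18 of 30 members were higher and none was lower, or 22 adjusted over the list alone (median log2 fold change 0.37, camera adjusted p = 6.9e-08, and adjusted p = 0.046 with an estimated correlation). TYMS, thymidylate synthase, rose 1.7-fold from 134 ± 7.8 to 227 ± 5.7 CPM, and MCM4, a subunit of the replicative helicase, rose 1.53-fold. In the G2 and mitosis list 16 of 29 rose and none fell, or 19 adjusted over the list alone (camera adjusted p = 3.57e-07, and adjusted p = 0.123 with an estimated correlation). MKI67, the proliferation marker Ki-67, rose 1.87-fold and the mitotic kinesin KIF20A rose 1.69-fold. Genes of homologous recombination and the Fanconi pathway rose in 8 of 26 cases, with 8 also over the list alone and none lower (camera adjusted p = 0.0268, and adjusted p = 0.22 with an estimated correlation), FANCD2 by 1.61-fold. With a mean FPKM of at least 5, which left 9 members, that list had a median log2 fold change of -0.04 and was not called (camera adjusted p = 0.43). Base excision repair as a list was not called (camera adjusted p = 0.245): 6 of 26 members rose and 3 fell, or 7 and 3 adjusted over the list alone. Without shControl 2 it was called as higher, at a median log2 fold change of 0.1 (camera adjusted p = 0.0453). PARP1 and PARP2, which bind DNA breaks, rose 1.47-fold and 1.65-fold, and the flap endonuclease FEN1 rose 1.47-fold.

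Heat shock genes rose in 13 of 18 cases and none fell, while 13 were higher and 1 lower when adjusted over the list alone (median log2 fold change 0.53, camera adjusted p = 9.18e-08, and adjusted p = 0.046 with an estimated correlation). HSP90AA1 rose 1.77-fold from 1118 ± 138 to 1980 ± 199 CPM and HSPA8 rose 1.52-fold. HSPA1A and HSPA1B rose 2.24-fold and 2.17-fold, but they are near-identical copies and the split between them is uncertain. Cholesterol synthesis and uptake genes rose in 11 of 22 cases with none lower, or 12 adjusted over the list alone (camera adjusted p = 5.29e-05, and adjusted p = 0.0816 with an estimated correlation), INSIG1, a sterol-responsive regulator, by 1.85-fold. Of fatty acid synthesis genes 7 of 18 rose and 2 fell, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.00811, and adjusted p = 0.123 with an estimated correlation), with ACACA, an acetyl-CoA carboxylase, 1.84-fold higher. Cytosolic ribosomal protein genes fell in 21 of 36 cases and none rose, or 25 adjusted over the list alone, at a median log2 fold change of -0.29 (camera adjusted p = 4.33e-07, and adjusted p = 0.399 with an estimated correlation). RPS16 fell 1.69-fold and RPLP0 1.44-fold, and processed pseudogenes share sequence with these genes. The level of both was highest in shControl 2, the outlying control, and without it the list median was -0.24 and the call stayed. Nuclear genes of oxidative phosphorylation fell in 13 of 34 cases and none rose, also over the list alone (camera adjusted p = 0.00147, and adjusted p = 0.53 with an estimated correlation), COX5B by 1.71-fold, and without shControl 2 the median log2 fold change of this list went from -0.24 to -0.17 and the call stayed.

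The largest rises included LGR5, a receptor for R-spondins that overlaps the more abundant TSPAN8 on the opposite strand, from 1.34 ± 0.13 to 11.6 ± 0.72 CPM (8.63-fold) and SHH, the sonic hedgehog ligand, from 4.49 ± 0.76 to 38.2 ± 4.0 CPM (8.5-fold). MARCKS, a substrate of protein kinase C, rose 7.2-fold and FBN2, a fibrillin, rose 4.78-fold from 63.9 ± 2.8 to 305.5 ± 34.2 CPM. HUNK, AP3B2, MRGPRX3, NDRG4, FAM216B, SNAI2 and TGM1 rose between 3.84-fold and 6.71-fold. PPP1R14C rose 4.7-fold, a call lost with robust dispersions and with no FPKM filter (adjusted p = 0.0561 and 0.066 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its log2 fold change was 2.23, and 3.32 without shControl 1. Other large falls were those of ESM1, a proteoglycan, at 19.5-fold and PDK4, a pyruvate dehydrogenase kinase, at 18.5-fold. ZBTB32 fell from 8.60 CPM to 0.07 CPM and PLAAT4 from 3.36 to 0.12 CPM, both close to the detection limit in shAPE1. The log2 fold change of ZBTB32 was -6.90, and -7.51 without shAPE1 3. BEST1, which overlaps FTH1, met the rule for a large fall but is uncertain: 4492 of its control counts came from shControl 3, against 122 and 104 in the other controls and 20 to 46 in shAPE1. Without shControl 3 its mean FPKM was 0.1, under the limit for testing.

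No call was made for the lists of hypoxia targets (camera adjusted p = 0.441), STAT3 targets (0.68), NRF2 targets (0.947), antioxidant enzymes (0.222), ferroptosis (0.412), apoptosis (0.0975), nucleotide excision and mismatch repair (0.243), end joining (0.783), or autophagy and lysosome (0.052, with 11 of 30 members lower and 0 higher). The autophagy list was called in 7 alternatives, among them quantile scaling (camera adjusted p = 0.0413) and no FPKM filter (0.00898). Nor was one made for epithelial (0.292), mesenchymal (0.211), WNT (0.799), Notch (0.301), glycolysis (0.227), ribosome biogenesis (0.245), mitochondrially encoded (0.19), histone (0.783), nuclear non-coding RNA (0.245), neuroendocrine (0.132), erythroid and hepatocyte (0.799) or APE1 partner lists (0.557). Without shControl 2 camera called the epithelial (adjusted p = 0.0384), glycolysis (0.0256), neuroendocrine (0.0467) and nuclear non-coding RNA lists (0.0467), and without shControl 1 the mesenchymal list (0.0486). The test fry, which asks another question, called the lists of hypoxia and STAT3 targets, ferroptosis, apoptosis, autophagy, ribosome biogenesis, mitochondrially encoded, nuclear non-coding RNA, neuroendocrine and APE1 partner genes. Several of the uncalled lists held members that moved in opposite directions. Among NRF2 targets AKR1B10, an aldo-keto reductase, rose 2.55-fold and HMOX1, heme oxygenase, fell 1.99-fold, and the list had 5 members higher and 4 lower of 29. Among WNT targets LGR5 rose while DKK1, a secreted WNT antagonist, fell 6.85-fold. Keratins KRT8 and KRT18, which overlap on opposite strands, rose 2.13-fold and 1.9-fold while KRT7 fell 2.02-fold. Of mesenchymal genes 3 rose and 7 fell of 20, FN1, fibronectin, rising 2.06-fold and CCN2 and TWIST2 falling 2.37-fold and 2.06-fold. Of fibroblast markers 1 was tested, LUM at 4.74 and 6.03 CPM (adjusted p = 0.201 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and 0 endothelial and 0 alveolar markers reached the limit for testing. Of 5 tested neuroendocrine markers 3 rose and 0 fell, or 3 and 1 adjusted over the list alone, with CHGA 2.4-fold higher. Of 5 tested erythroid and hepatocyte markers 1 fell and 0 rose, and of 5 tested nuclear non-coding RNAs 1 fell and 0 rose.

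**Figure D3:**
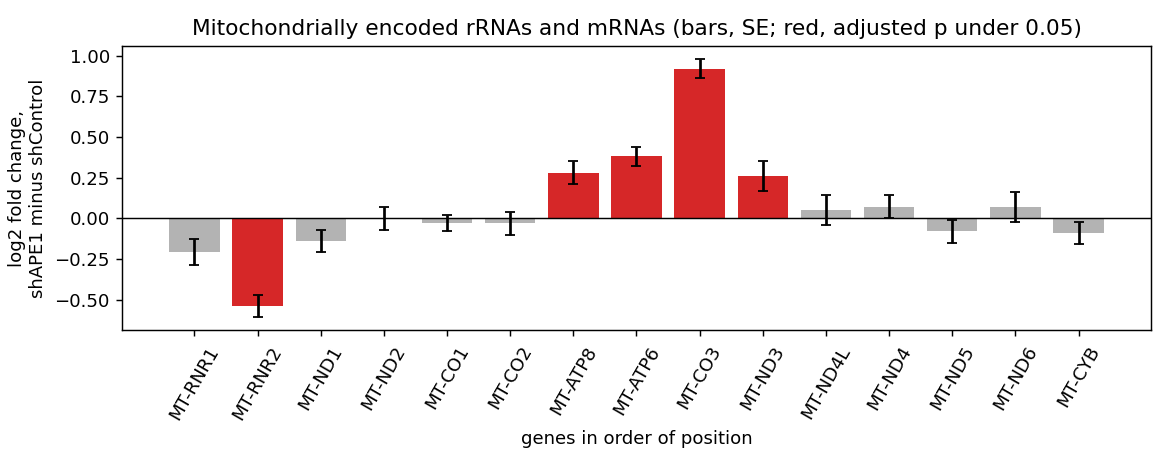
Log2 fold changes (shAPE1 minus shControl, vertical axis) with SE of the mitochondrially encoded ribosomal RNAs and mRNAs in order of position, red where adjusted p was under 0.05. MT-CO3 stands at 0.92 with its neighbours MT-ATP8, MT-ATP6 and MT-ND3 at 0.28, 0.38 and 0.26, and MT-RNR2 at -0.54.

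Of 40 lists tested, 17 were called, 6 higher and 11 lower, and 5 of these were called with an estimated correlation: type I interferon, integrated stress response, immediate early, heat shock, and S phase. Of 3064 annotation terms 343 were called, 230 higher and 113 lower, led by the Reactome response of GCN2 to amino acid deficiency (58 of 99 genes lower, 3 higher, camera adjusted p = 2.86e-10, and adjusted p = 0.634 with an estimated correlation). Of those 58 genes 46 encode ribosomal proteins and 6 are in the integrated stress response list, so this term largely repeats the ribosomal protein fall. Lower members of the terms of selenocysteine synthesis and of translation elongation and termination that follow it number 49 to 51 each, of which 46 each encode ribosomal proteins. With an estimated correlation camera called 0 terms, with 265 at an unadjusted p under 0.05. Other splits of the 6 libraries into 3 and 3 gave up to 15 called lists and 153 called terms at the preset correlation, and 0 called genes. Each of these splits mixed libraries of both groups, so these are not counts for groups without a difference.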

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

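Scaling by total counts and leaving out read-through genes were chosen after the data were seen. APEX1 fell and passed the threshold in all 24 alternatives, with log2 fold changes from -0.57 to -0.44. The count of called genes was 2041 to 3937 with 1 library left out, lowest without shAPE1 1 and highest without shControl 2. The fits have fewer samples, and 63.6% of the 3128 calls were kept without shAPE1 1. With no FPKM filter 2210 genes were called and 55.6% of the 3128 calls were kept. DESeq2 called 3653 genes, and limma's voom with quality weights called 4399, the most of any alternative. The count at 2-fold was 227 with limma and a pseudocount of 1, which shrinks low genes, and 154 with a mean FPKM of at least 5, 901 with at least 0.1 and 757 with no filter, where fewer or more genes were tested. With 1 library left out it was 427 to 448. Called lists numbered 5 with an estimated correlation and 27 with fry, which tests another hypothesis, and 17 to 23 with 1 library left out. Called terms numbered 0 with an estimated correlation, 527 with no filter, and 306 to 424 with 1 library left out. Robust and untrended dispersions do not enter the list and term tests, so those counts could not move. Voom's quality weights and limma's variance trend do not enter those tests either, so the lists and terms did not test these settings. For named genes the threshold was lost 39 times with all libraries and 26 times with 1 left out, and 0 directions reversed. For lists 14 calls were lost and 14 gained with all libraries, and 8 were gained with 1 left out. No scaling moved the median of all genes by over 0.1. Same-numbered libraries correlated in their deviations at 0.183, 0.084 and 0.011, and differently numbered libraries of the groups at -0.171 to 0.08. With the replicate block 3990 genes were called, and a shared batch is neither shown nor excluded. Depth limits values under 0.047 CPM.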

Other observations

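The tests of the mitochondrial genes, of the splits at 2-fold, of the SD of read-through genes with their components and of the 4 leukocyte genes as a set were chosen after the results were seen, as was the use of the adjusted p for scaling and for GC content in the interferon list. Within the mitochondrial genome, MT-CO3 (chromosome MT, 9207 to 9990), a subunit of cytochrome c oxidase, rose 1.89-fold from 4331 ± 104 to 8184 ± 154 CPM, with an adjusted p of 9.46e-08 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Its neighbour MT-ATP6 rose 1.3-fold, and MT-ATP8 and MT-ND3 rose 1.21-fold and 1.2-fold, calls that were lost in several alternatives. MT-RNR2, the large ribosomal RNA, chosen after its values were seen, fell from 13910 to 9549 CPM, and MT-TG, chosen in the same way, fell from 12.65 to 7.34 CPM (adjusted p = 0.00381 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

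The real split of the 6 libraries gave 3128 called genes and 412 at 2-fold, and the highest of the others gave 0 and 0 by edgeR's quasi-likelihood test, with 535 genes at an unadjusted p under 0.05 against 4382. The real split gave 17 lists and 343 terms, and the highest of the others 15 and 153. In each case 1 of 10 splits, the real one, reached the real count, and 10 splits are too few for a share under 0.05. Every other split mixed libraries of both groups, so part of the real difference lay between its sides and part within them. That left little room for called genes, and the lists and terms are not counts for sides without a difference. At the preset correlation, lists and terms were called in such splits although 0 genes were called.

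The type I interferon list fell by a median log2 fold change of -0.99. Leukocytes in the controls are argued against, since PTPRC, CD3E, TYROBP and FCER1G summed to 2.38 CPM there, 0.293% of the 814 CPM that the list lost, and a single control library likewise, since the highest adjusted p without 1 control was 3.74e-12 by camera with Benjamini-Hochberg adjustment. The median nearest 0 over 5 other scalings was -0.9 and the median without a trend on GC content and transcript length was -1.01. The bound of -1 set beforehand for both was met without the trend and missed over the scalings. It was too strict for the scalings, because the unaltered median was already above it. The list's highest adjusted p by camera was 2.91e-14 over the scalings and 1.55e-16 without the trend. Camera compares the list with the other genes, so a shift shared by all genes hardly moves its p. That p therefore cannot decide on scaling. The medians argue against a choice among these scalings as the whole cause, and the median and p without the trend argue against that trend as the whole cause. The knockdown, a state of the control cells alone and effects of a hairpin beyond APEX1 all stay open and untested. The same holds for the other lists and genes that differed between the groups. No cells without a hairpin were analysed here. The labels do not tell separate hairpins against APE1 apart and name no cells with APEX1 restored.

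Of 37 tested read-through genes, which span neighbouring genes, 6 were called. The groups overlapped in 66.7% of the 6, which fits counts that are erratic between replicates for these, but not for PMF1-BGLAP and ST20-MTHFS, chosen after their values were seen, whose groups did not overlap. In 5 with component genes in the table, reads moved between models would make the sum of both vary less between libraries than the components alone. TMEM189-UBE2V1, chosen after its values were seen, had 1435 counts in shAPE1 2 and 0 in the other libraries. The median ratio of these SDs was 0.945, with 4 of 5 under 1. The ratios ran from 0.264 for HNRNPUL2-BSCL2, chosen after its values were seen, to 1.98 for ST20-MTHFS. Over these few genes as a set, moved reads thus cannot be told apart from unrelated counts, and no biological explanation was tested.

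For the rise of MT-ATP8, MT-ATP6, MT-CO3 and MT-ND3, a larger share of mitochondrial RNA as the whole cause is argued against. The summed CPM of all mitochondrial genes had a log2 ratio of 0.01 (SE 0.03) between groups, against 0.26 for the smallest of the 4 rises. That sum includes MT-RNR2, which fell from 13910 to 9549 CPM, so it does not give the share of the mRNAs alone. The list of 13 mitochondrially encoded mRNAs had a median log2 fold change of 0.05. For MT-ATP6, reads moved from its copy on chromosome 1 are argued against, since MTATP6P1 did not fall (log2 fold change 0.39) and the sum of both changed by 0.38, as MT-ATP6 did alone. Copies of MT-CO3, MT-ATP8 and MT-ND3 elsewhere in the genome were not examined. MT-TG, a transfer RNA gene between MT-CO3 and MT-ND3, was lower (log2 fold change -0.78). MT-ATP8 and MT-CO3 both overlap MT-ATP6, MT-CO3 only at base 9207, so reads of these genes could be assigned to either. MT-ATP8, MT-ATP6 and MT-CO3 all rose (log2 fold changes 0.28, 0.38 and 0.92). That argues against reads moved among them as the cause of their joint rise, though not of its split. No biological explanation was tested.

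Across 10794 genes, which are not independent replicates, the log2 fold change had a Spearman correlation of -0.277 with GC content and 0.192 with transcript length. With that trend removed 20 lists were called, 7 higher and 13 lower. The call of homologous recombination and the Fanconi pathway was lost (adjusted p = 0.0725 by camera with Benjamini-Hochberg adjustment, median log2 fold change 0.22 before and 0.16 after). Those of autophagy and lysosome, apoptosis, mitochondrially encoded and neuroendocrine genes were gained.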
